A study of Mus musculus with 8 samples.

How the data were processed

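Messenger RNA abundance was measured by RNA sequencing in 8 liver samples of mice, 4 labelled with the adeno-associated viral vector AAV2/9-SA and 4 with AAV2/9-Ctrl. Per the labels' protocols, RNA was taken from frozen liver with RNAiso Plus and libraries were made with a NEBNext Ultra kit. The labels do not describe it as strand-specific, so reads of a gene and of an antisense neighbour may not be told apart. The deposited count table holds whole-number read counts per gene for the 8 libraries, with no normalization. The deposited FPKM table holds FPKM values for fewer genes, as computed by the authors. Per the submitters' processing notes, FastQC 0.19.7, HISAT2 and StringTie 2.2.1 were used, and the genome builds GRCm39 and mm10 are both named without a role. Which program counted the reads and against which build is not given in the sources used here, so no coordinates are printed.

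The count table lists 31910 genes, of which 17681 had a count in at least 1 library. The FPKM table lists 9265 rows, all above 0 in every library, and 8638 of its symbols are in the count table. Across the 7940 tested genes in both tables, the deviations of a library from the gene mean correlated only at 0.26 to 0.46 between FPKM and counts. This correlation is across genes, which are not independent replicates. The FPKM values served only as an alternative.

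Samples were grouped by their titles. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the filterByExpr filter, which left 12358 genes. A Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Levels are TMM-normalized CPM, that is counts of a gene over the counts of all tested genes in its library multiplied by the TMM factor, times 1e6. The test compared 4 libraries with 4 without a block.

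Before the data were examined, 38 lists of genes (pathways, cell type markers and markers of other tissues) were fixed. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 38 lists. The same lists were tested with an estimated correlation and with fry. List means were compared by an exact permutation test over the libraries, which cannot go below 0.0286 with 4 against 4. Named genes were fixed by rule. The first part takes the 12 largest changes in each direction among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups, unnamed gene models and pseudogenes left out. Only 2 genes met it. The second part takes up to 4 members with the smallest p from each list, and the third takes Acaca and Acacb, since the series title concerns acetyl-CoA carboxylase. For lists that did not pass, the text prints only some of the second-part genes. A few further genes were chosen after their values were seen, and the text says so where they appear.

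The edgeR fit was tested on simulated counts drawn from the means, library sizes and dispersions of the SA against Ctrl comparison, with 200 genes changed. Of 12213 simulated genes tested, 67% of those changed 2-fold and 96.9% of those changed 4-fold were called, with 12 false calls among 173. The simulated genes were drawn independently of each other and no library was set apart. These shares may therefore not hold for the real libraries. Total counts ranged from 14114145 to 15922829 in 7 libraries and reached 28184001 in SA 4. The biological coefficient of variation was 22.6%. Each of the 8 samples has its own title and its own number in the labels, which do not state that these stand for 8 animals, so p-values measure the spread between these samples. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 24.6 over genes with at least 40 counts in total.

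Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, RLE and upper quartile factors, no low-count filter, a filter of CPM of at least 1 in at least 4 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 0.5 in at least 4 libraries, the first also without that filter, the omission of each library, and the replicate number as a block. A fit with the log2 mitochondrial share of each library as a covariate was added after seeing the data.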

Results

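The series compared livers of mice that received 1 of 2 adeno-associated viral vectors, AAV2/9-SA or AAV2/9-Ctrl. Its title concerns a bacterial protein that binds acetyl-CoA carboxylase in mice with steatohepatitis, a fatty liver with inflammation. The series design describes a high-fat diet of 24 weeks, a high-fat, high-cholesterol diet with sugared water of 16 weeks and a chow diet, with 4.8e10 vector genomes per mouse injected after 7 weeks of feeding. The labels of the 8 libraries do not state which diet each mouse had. Each group had 4 libraries. Total counts were 14359368, 14995984, 15328093 and 15252046 in Ctrl 1 to 4 and 14763973, 15922829, 14114145 and 28184001 in SA 1 to 4. Correlations of log2 CPM between libraries of a group were 0.95 to 0.98, and between groups 0.96 to 0.98. Mitochondrially encoded transcripts took 9.23% of the counts in Ctrl 4 and 3.55% to 4.87% in the other 7 libraries.

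The first question was which single genes differed after AAV2/9-SA. Cyp2c40, a cytochrome P450 of the 2C subfamily, rose from 0.823 ± 0.259 CPM (SD, n = 4) to 7.15 ± 2.27 CPM (SD, n = 4), a log2 fold change of 3.10 ± 0.33 (SE; edgeR quasi-likelihood test, adjusted p = 0.00604). Adgrv1, an adhesion G protein-coupled receptor, fell from 27.7 ± 7.33 CPM to 5.04 ± 2.87 CPM (SD, n = 4 in each group), a log2 fold change of -2.47 ± 0.33 (SE; edgeR, adjusted p = 0.0367). In both genes the 4 SA libraries did not overlap the 4 Ctrl libraries. Cyp2c40 belongs to a family of near-identical genes, so its count is uncertain. Of 3 relatives chosen after their values were seen, Cyp2c69 had a log2 fold change of 2.48 (edgeR, adjusted p = 0.342), and the more abundant Cyp2c67 and Cyp2c68 had 0.20 and 0.52. With DESeq2 Cyp2c69 passed, at 2.51 (adjusted p = 0.0126).

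Acaca and Acacb, which encode the 2 acetyl-CoA carboxylases, did not pass the test. Acaca was at 142.7 ± 35.94 CPM in Ctrl and 131.5 ± 21.69 CPM in SA (SD, n = 4), a log2 fold change of -0.12 ± 0.19 (SE; edgeR, adjusted p = 0.996). Acacb was at 193.4 ± 54.55 CPM in Ctrl and 183.8 ± 34.65 CPM in SA (SD, n = 4), a log2 fold change of -0.07 ± 0.21 (SE; edgeR, adjusted p = 0.996). Both values turned positive without Ctrl 3, at 0.00904 for Acaca and 0.116 for Acacb, and Acacb also without SA 4, at 0.0469.

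Of 12358 genes tested, 1 was higher and 1 lower in SA (edgeR, adjusted p under 0.05). At an unadjusted p under 0.05 there were 767 genes, 360 higher and 407 lower. The 4 SA libraries lay above all Ctrl libraries for 205 genes and below them for 181, together 3.12% of genes against 2.86% by chance. DESeq2 called 23 genes higher and 39 lower, including both genes above. Of the list members named below, it called Lox, Col5a2, Mmp13, Gpnmb, Cx3cr1, Cd8a, Gzma, Ighg2c, Elovl5, Fads2, Saa4, Socs3, Abcc4, Aqp7 and Ccnd1. Without Ctrl 4, which carries the high mitochondrial share, neither gene passed (edgeR, adjusted p = 0.0602 for Cyp2c40 and 0.148 for Adgrv1). Adgrv1 also did not pass without Ctrl 1, Ctrl 2, SA 2, SA 3 or SA 4 (adjusted p = 0.0970, 0.0544, 0.242, 0.126 and 0.182). Without SA 1 there were 13 genes higher and 6 lower, and without Ctrl 2 there were 1 higher and 2 lower.

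**Figure D1:**
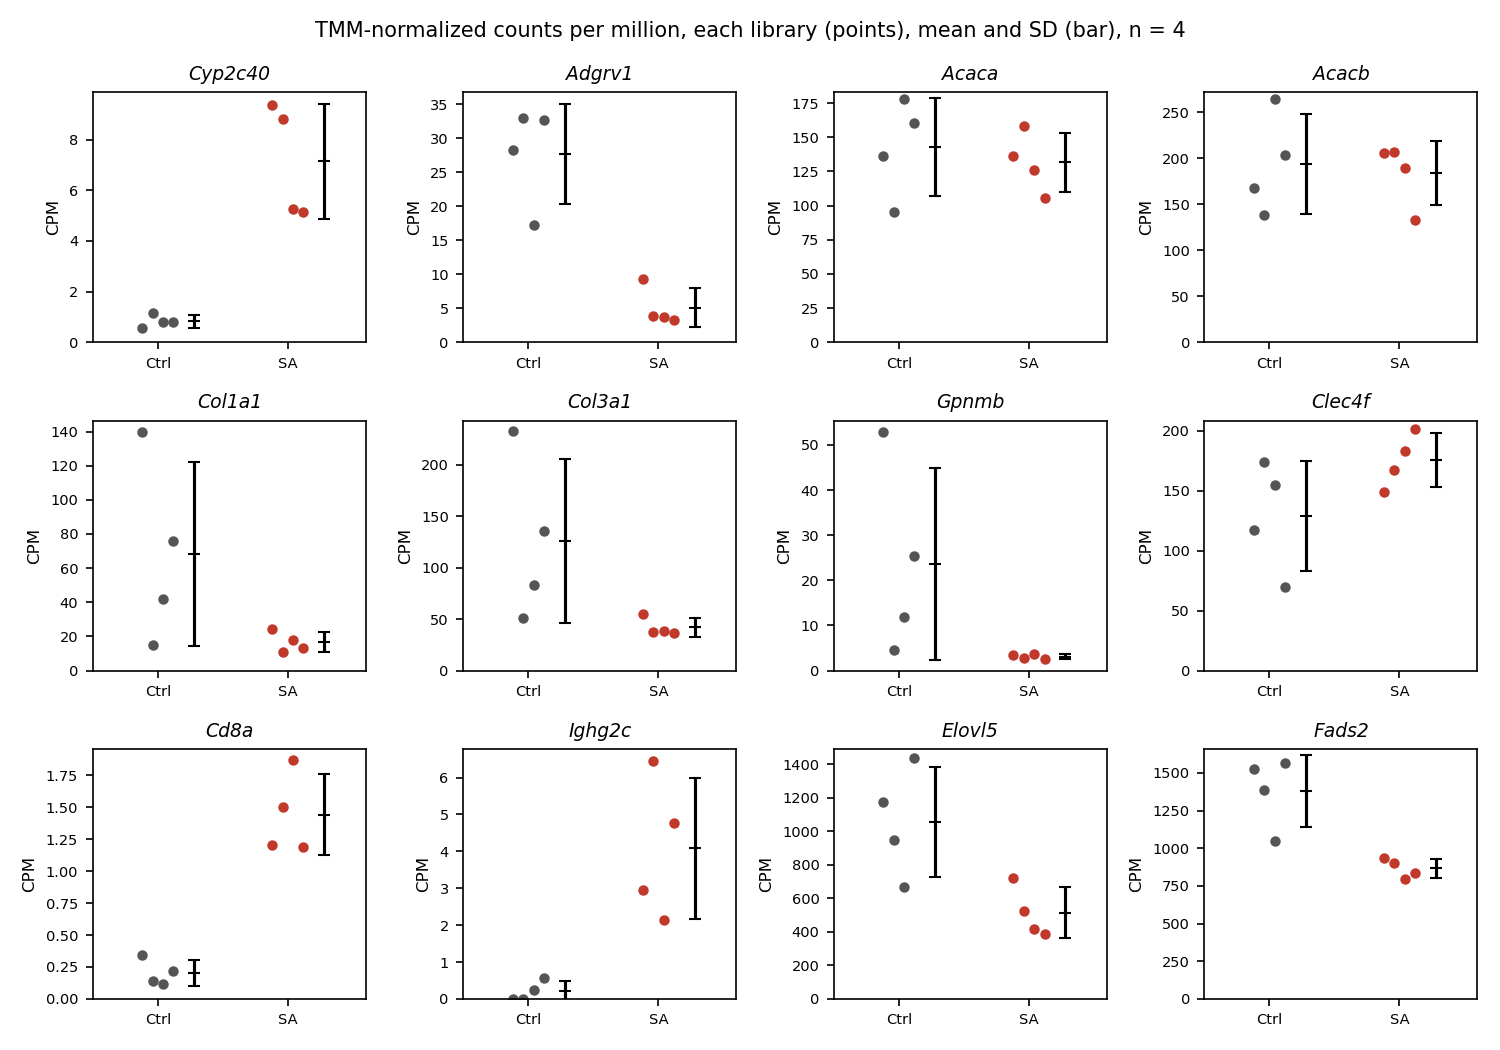
Normalized counts in CPM (linear axis from 0) of 12 genes in the 4 Ctrl and 4 SA libraries, as points, with the mean and SD of each group beside them. The 4 SA libraries lie above the Ctrl libraries for Cyp2c40 and below them for Adgrv1, while Acaca and Acacb overlap.

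Most genes listed for fibrosis and the extracellular matrix were lower in SA. Of 29 tested members of the fibrosis and matrix list, 28 had a negative log2 fold change, with a median of -1.10 (camera, adjusted p = 1.84e-25; adjusted p = 0.253 with an estimated correlation). With edgeR no member passed over all genes, and 21 passed, all lower, when adjusted over the list alone. With DESeq2 Lox (adjusted p = 0.00278) and Col5a2 (adjusted p = 0.0236) passed over all genes. With edgeR Lox passed without SA 1 (adjusted p = 0.04997). The listed Mmp13 and the unlisted genes that follow were chosen after their values were seen. Mmp13 passed with DESeq2 at -1.76 (adjusted p = 0.0418). Unlisted, Postn (-0.87) and Tnc (-2.53) passed lower with DESeq2 (adjusted p = 0.00439 and 0.0111). The collagens Col15a1 (0.97) and Col27a1 (0.83) passed higher with DESeq2 (adjusted p = 0.0380 and 0.0365). Col1a1 and Col3a1, which encode fibrillar collagens, had log2 fold changes of -2.04 ± 0.51 and -1.58 ± 0.36 (SE). Lox, a collagen cross-linking enzyme, had -3.42 ± 0.67 (SE), and Col5a2 had -1.36 ± 0.35 (SE) but -0.83 without Ctrl 1. Lox was at 1.61 ± 1.01 CPM in Ctrl and near the floor in SA, at 0.158 ± 0.167 CPM (SD, n = 4). Col1a1 was at 68.17 ± 53.93 CPM in Ctrl and 16.60 ± 5.942 CPM in SA (SD, n = 4). The control libraries were spread widely, since the list median deviated from the mean over libraries by 1.43 in Ctrl 1, 0.62 in Ctrl 4, 0.33 in Ctrl 3 and -0.37 in Ctrl 2, against -0.28 to -0.67 in SA. The list mean gave p = 0.0857 in an exact two-sided permutation test, and without Ctrl 1 the median fold change was -0.61.

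Markers of hepatic stellate cells, the main collagen-producing cells of the liver, were lower by less. Of 13 members 12 had a negative value, with a median of -0.25 (camera, adjusted p = 0.0163; adjusted p = 0.253 with an estimated correlation). Dcn had a log2 fold change of -0.67, Pdgfrb -0.75 and Des -0.46, while Vipr1 had 0.40. Pdgfrb was at 32.6 CPM in Ctrl 1 and 8.55 to 19.4 CPM in the other Ctrl libraries. Des was at 12.3 CPM in Ctrl 1 and 5.31 to 8.27 CPM in the other Ctrl libraries. Without SA 4 the list did not pass (adjusted p = 0.0715). No member of the stellate list passed when adjusted over the list alone. Markers of bile duct cells had a median of -0.85 over 9 members (camera, adjusted p = 0.00605; adjusted p = 0.382 with an estimated correlation), with Epcam at -1.06, Krt19 at -1.26, Spp1 at -0.89 and Prom1 at -0.85. No bile duct member passed over the list alone, and the call ended without Ctrl 4 (adjusted p = 0.111). Without Ctrl 1 the bile duct median was -0.54 and Krt19 had -0.67. Spp1 is also in the matrix list, so the bile duct and matrix calls share a gene.

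Among macrophage genes, markers of monocytes and recruited macrophages were lower and those of resident Kupffer cells higher. The recruited list had a median of -0.54 over 17 members, 14 of them negative (camera, adjusted p = 4.22e-07; adjusted p = 0.377 with an estimated correlation). Its 4 members past the threshold when adjusted over the list alone were Gpnmb at -2.93, Cx3cr1 at -1.78, Ccr2 at -1.43 and Mmp12 at -1.48. Mmp12 is also in the matrix list. Without Ctrl 2 Gpnmb and Mmp12 passed over all genes (edgeR, adjusted p = 0.0135 each), and without Ctrl 1 Ccr2 had -0.93. Gpnmb, a gene of lipid-laden macrophages, was at 23.6 ± 21.3 CPM in Ctrl and 3.11 ± 0.475 CPM in SA (SD, n = 4). The median deviation was 0.96 in Ctrl 1 and at most 0.23 in every other library, and without Ctrl 1 the median fold change was -0.26. Kupffer markers were positive in 11 of 12 members, with a median of 0.28 (camera, adjusted p = 0.000207; adjusted p = 0.272 with an estimated correlation). Timd4 had 0.71, Cd163 0.64, Clec4f 0.45 and Slc40a1 0.28, and no member passed over the list alone.

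Of the lymphocyte markers with enough counts to be tested, 15 of 18 were higher in SA. The filter asked for enough counts in at least 4 libraries. Cd8a, Gzma and Ighg2c were low in Ctrl and entered the test through SA, while genes as low in both groups were left out. The share of 15 of 18 and the list calls below therefore do not describe all listed lymphocyte genes. The T and NK cell list had only 7 of its 24 genes tested, with a median of 0.45 and 6 members positive (camera, adjusted p = 2.11e-06; adjusted p = 0.0933 with an estimated correlation). Cd8a, a co-receptor of cytotoxic T cells, was near the floor in Ctrl, at 0.2038 ± 0.1004 CPM, and at 1.44 ± 0.317 CPM in SA (SD, n = 4). Its log2 fold change was 2.78 ± 0.45 (SE; edgeR, adjusted p = 0.0819). Gzma, a granzyme, had 2.41 ± 0.49 (SE; edgeR, adjusted p = 0.227), and these 2 genes passed when adjusted over the list alone. Gzma was at 0.469 ± 0.357 CPM in Ctrl and 2.56 ± 0.533 CPM in SA (SD, n = 4). Nkg7 had 1.18 and Lck 0.45. The other members, chosen after their values were seen, were Cd4 at 0.35, Trbc2 at 0.14 and Zap70 at -0.28. Of the T cell genes with too few counts, also chosen afterwards, Cd3e went from a mean of 0.317 CPM in Ctrl to 0.167 CPM in SA and Cd2 from 0.634 to 0.515 CPM, while Cd3d went from 0.148 to 0.436 CPM and Cd3g from 0.431 to 0.772 CPM (n = 4 in each group). The B and plasma cell list, with 11 of 19 genes tested, had a median of 0.29 and 9 members positive (camera, adjusted p = 0.00232; adjusted p = 0.193 with an estimated correlation). Ighg2c, an immunoglobulin heavy chain constant gene, had 4.29 ± 0.70 (SE; edgeR, adjusted p = 0.0819) and alone passed over the list. Without SA 1 it passed over all genes (edgeR, adjusted p = 0.04997). Ighg2c was near the floor in Ctrl, at 0.204 ± 0.272 CPM with 0 in Ctrl 1 and Ctrl 2. In SA it was at 4.08 ± 1.92 CPM (SD, n = 4 in each group). Cd22 had 0.89 and Igha 0.99, while Xbp1 had -0.37. For both lists, as for the stellate and circadian lists, the mean gave the smallest p an exact permutation test allows, 0.0286. Without Ctrl 2 the T and NK median was 1.18 over 8 tested members, and the B and plasma median was 0.45 without Ctrl 1, 0.49 without Ctrl 3, 0.45 without Ctrl 4 and 0.50 without SA 3. The neutrophil list had a median of -0.64 over the only 4 of its 14 genes tested, with S100a8 at -1.46, S100a9 at -0.86, Mmp9 at -0.42 and Csf3r at -0.17 (camera, adjusted p = 0.0202; adjusted p = 0.377 with an estimated correlation). That call ended without Ctrl 3 (adjusted p = 0.115) or SA 2 (adjusted p = 0.0582, median -0.41), and Csf3r turned to 0.0957 without Ctrl 3.

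**Figure D2:**
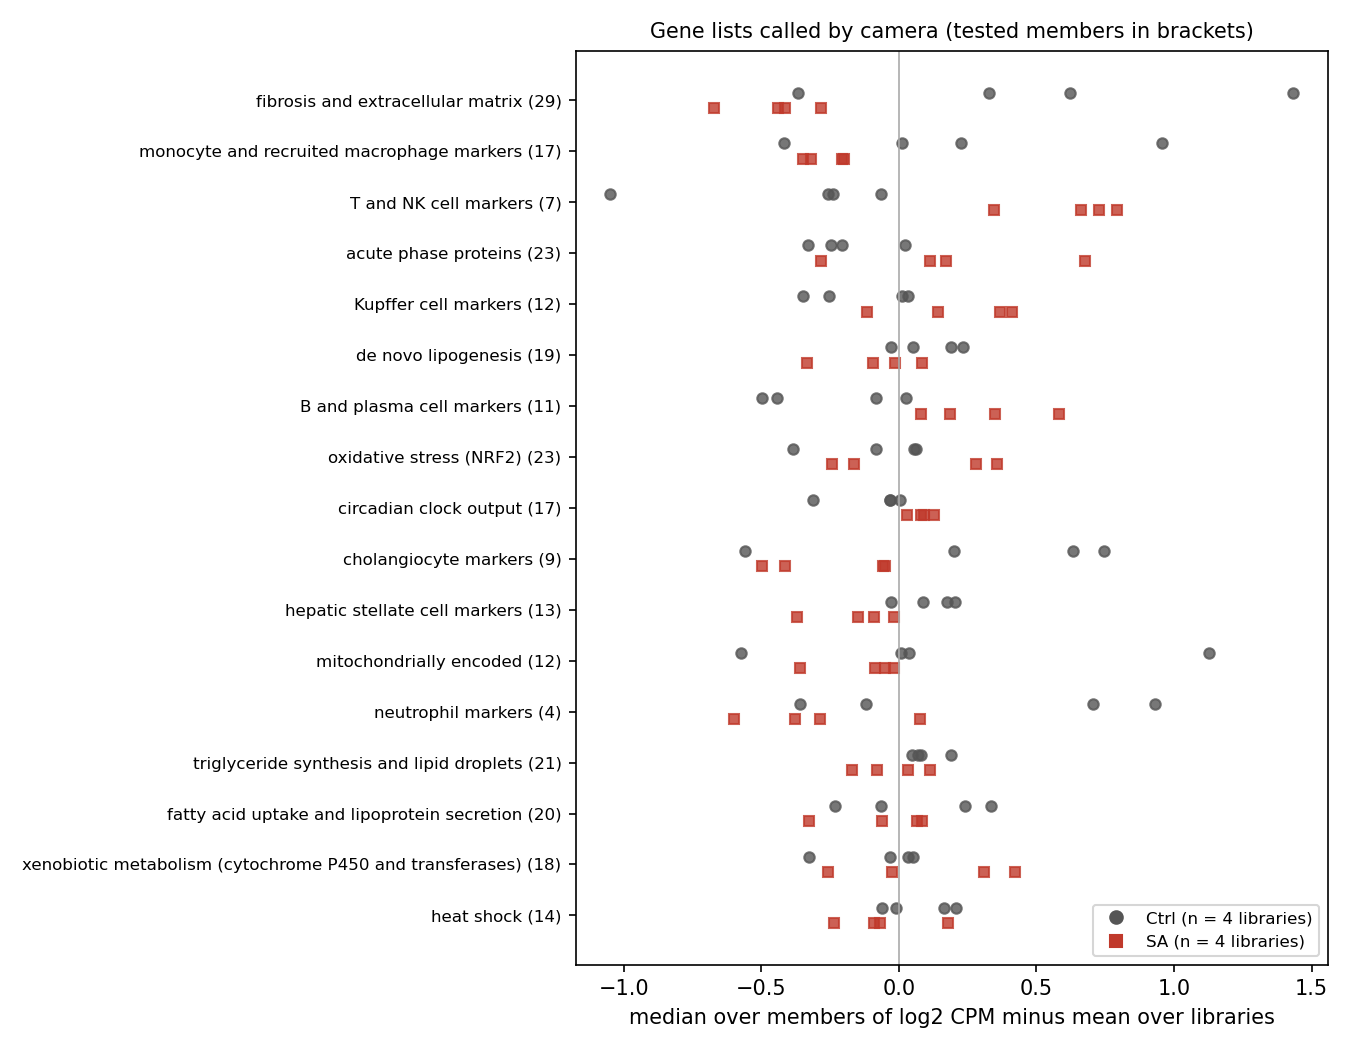
Each of the 17 gene lists past the camera threshold at the preset correlation, with the median over its members of log2 CPM minus the gene's mean over 8 libraries (horizontal axis) for the 4 Ctrl (circles) and 4 SA (squares) libraries. For the matrix list Ctrl 1 stands at 1.43 and Ctrl 2 at -0.37, inside the range of the SA libraries, while for the T and NK list the groups do not overlap.

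Lists named for lipogenesis and triglyceride synthesis had slightly negative medians. De novo lipogenesis had a median of -0.12 over 19 members, 15 of them negative (camera, adjusted p = 0.00108; adjusted p = 0.377 with an estimated correlation). Elovl5, which elongates polyunsaturated fatty acids, went from 1057 ± 327.3 CPM in Ctrl to 514.0 ± 151.6 CPM in SA (SD, n = 4), a log2 fold change of -1.04 ± 0.25 (SE). The fatty acid desaturase Fads2 had -0.67 ± 0.17 (SE), and Elovl5 and Fads2 passed when adjusted over the list alone. Fads1 had -0.37 and Srebf1, a transcription factor of lipid synthesis, -0.42. Elovl5, Fads2 and Fads1 were the only 3 members with an unadjusted p under 0.05 (edgeR). Acaca and Acacb, also members, had -0.12 and -0.07. The lipogenesis list mean gave p = 0.143 in an exact two-sided permutation test. The lipogenesis median was -0.21 without Ctrl 2, -0.20 without SA 1, -0.23 without SA 2 and -0.19 without SA 4. Triglyceride synthesis and lipid droplet genes had a median of -0.09 over 21 members (camera, adjusted p = 0.0202; adjusted p = 0.377 with an estimated correlation), with Cidec at -0.94, Cidea at -1.14, Mogat1 at -0.88 and Pparg at -0.56 and none past the threshold over the list alone. That call ended without Ctrl 2 (adjusted p = 0.162) or SA 3 (adjusted p = 0.192), and its median was -0.14 without Ctrl 4 or SA 1. Fatty acid uptake and lipoprotein genes had a median of -0.15 over 20 members (camera, adjusted p = 0.0300; adjusted p = 0.559 with an estimated correlation). Apoa4, an apolipoprotein, had -1.60 and alone passed over the list. It did not pass over all genes (edgeR, adjusted p = 0.367) but did with the replicate number as a block (adjusted p = 0.0130). Fabp4 had -0.84, Cd36 -0.37 and Tm6sf2 0.40. Fabp4 was at 40.4 CPM in Ctrl 1, 13.5 to 21.8 CPM in the other Ctrl libraries and 10.4 to 15.1 CPM in SA. The call ended without Ctrl 1, Ctrl 2, SA 1 or SA 3 (adjusted p = 0.160, 0.207, 0.0531 and 0.254), with medians of -0.06 without Ctrl 1, -0.02 without Ctrl 2 and -0.06 without SA 3, while without Ctrl 4 the median was -0.25.

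Acute phase genes were higher, with 18 of 23 members positive and a median of 0.33 (camera, adjusted p = 2.63e-06; adjusted p = 0.377 with an estimated correlation). Saa4, a serum amyloid A gene, was at 416 ± 61.1 CPM in Ctrl and 836 ± 213 CPM in SA (SD, n = 4), a log2 fold change of 1.01 ± 0.20 (SE; edgeR, adjusted p = 0.227). Socs3, a feedback inhibitor of cytokine signalling, had 1.47, Itih4 0.72 and Mt1 0.96, and 3 members passed when adjusted over the list alone. Mt1 was at 318.4 CPM in SA 1 and 94.2 to 132.2 CPM in the other SA libraries. Without SA 1 the acute phase median was 0.09. Circadian clock genes had a median of 0.23 over 17 members (camera, adjusted p = 0.00557; adjusted p = 0.253 with an estimated correlation), with Tspan4 at 0.61, Nfil3 at 0.60, Lpin1 at 0.80 and Cry1 at 0.46, none past the threshold over the list alone. The circadian median was 0.07 without Ctrl 1 and 0.07 without SA 4. Cry1 was at 17.3 CPM in SA 4, 5.77 to 9.63 CPM in the other SA libraries and 6.82 to 7.72 CPM in Ctrl. NRF2 target genes had a median of 0.22 over 23 members (camera, adjusted p = 0.00319; adjusted p = 0.637 with an estimated correlation). Abcc4, an efflux transporter, had 1.54 and alone passed over the list, and without SA 1 it passed over all genes (edgeR, adjusted p = 0.0285). Aox1 had 0.54, Gstm1 0.83 and Gsta2 1.13, the last 0.61 without SA 4. The call ended without Ctrl 4 (adjusted p = 0.325) or SA 4 (adjusted p = 0.428, median -0.02), and without SA 3 the median was 0.34.

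Cytochrome P450 and transferase genes had a median of 0.30 over 18 members (camera, adjusted p = 0.0390; adjusted p = 0.637 with an estimated correlation), and the member with the smallest p went the other way, Sult1e1, an estrogen sulfotransferase, at -3.70 but -1.81 without Ctrl 2, the library with 12.3 CPM against 0.68 to 1.58 CPM in the other Ctrl libraries. Cyp1a1 had 1.13, Cyp2a5 1.23 (0.68 without SA 4) and Ugt2b5 0.40. The call ended without Ctrl 1, Ctrl 3, SA 2 or SA 4 (adjusted p = 0.288, 0.0793, 0.194 and 0.621), and without SA 4 the median was 0.13. Mitochondrially encoded genes had a median of -0.35, with all 12 members negative (camera, adjusted p = 0.0169; adjusted p = 0.720 with an estimated correlation), among them COX3 at -0.71, COX2 at -0.61, ATP6 at -0.51 and CYTB at -0.38. The share of mitochondrial counts was 5.51% ± 2.53 in Ctrl and 4.63% ± 0.305 in SA (SD, n = 4; exact two-sided permutation test, p = 0.857), and without Ctrl 4 the list median was 0.05 (adjusted p = 0.375). Without Ctrl 3 it was -0.54. Without SA 4 the mitochondrial list did not pass either (adjusted p = 0.167). Heat shock genes had a median of -0.12 over 14 members at the edge of the threshold (camera, adjusted p = 0.04996; adjusted p = 0.573 with an estimated correlation), with Hspb1 at -0.63, Cryab at -0.60, Hspa8 at -0.40 and Hsp90aa1 at -0.21. Leaving out Ctrl 2, Ctrl 3, Ctrl 4, SA 1, SA 2 or SA 3 ended that call (adjusted p = 0.203, 0.232, 0.0624, 0.448, 0.105 and 0.0502), and the heat shock median was -0.07 without Ctrl 3, -0.20 without Ctrl 1 and -0.19 without SA 4.

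Of the 38 lists, 7 were higher and 10 lower in SA with camera at the preset correlation, and none with an estimated correlation, where 6 had an unadjusted p under 0.05. Fry called 1 list, B and plasma cells (adjusted p = 0.0393). The other 21 lists did not pass with camera, and the closest were interferon response (median 0.10, adjusted p = 0.102), biotin-dependent carboxylases (median -0.11, adjusted p = 0.105) and oxidative phosphorylation (median -0.09, adjusted p = 0.105). Oxidative phosphorylation passed, lower, without Ctrl 3, Ctrl 4, SA 2 or SA 4 (adjusted p = 0.0107, 0.00167, 0.0320 and 0.00845), but its median was 0.00666 without Ctrl 2 (adjusted p = 0.821) and -0.0150 without SA 3 (adjusted p = 0.980). Interferon response passed, higher, without Ctrl 1, SA 2 or SA 3 (adjusted p = 0.0270, 0.0320 and 0.00372). Genes of cholesterol synthesis (median 0.07, adjusted p = 0.225), PPARalpha targets (median 0.07, adjusted p = 0.225), mitochondrial fatty acid oxidation (median -0.06, adjusted p = 0.465), bile acid synthesis (median 0.05, adjusted p = 0.574) and gluconeogenesis and glycolysis (median -0.06, adjusted p = 0.320) did not pass. Of these, cholesterol synthesis passed, higher, and mitochondrial oxidation, lower, without SA 4 (adjusted p = 0.0342 and 0.0337), and PPARalpha targets, higher, without SA 1 (adjusted p = 0.000587). Aqp7, the PPARalpha member with the smallest p, went the other way, at -3.55 (edgeR, adjusted p = 0.122), and passed with DESeq2 (adjusted p = 0.000314). It was at 2.09 CPM in Ctrl and near the floor in SA, at 0.184 CPM (means, n = 4). The bile acid median ran from -0.09 without Ctrl 1 to 0.12 without Ctrl 4, and that of gluconeogenesis and glycolysis from -0.16 without SA 4 to 0.01 without SA 3. Hepatocyte markers (median 0.08, adjusted p = 0.225), periportal genes (median 0.08, adjusted p = 0.491), pericentral genes (median 0.00, adjusted p = 0.931), endothelial markers (median -0.10, adjusted p = 0.155) and erythroid markers (median 0.43, adjusted p = 0.409) did not pass. Pericentral genes passed, higher, without Ctrl 2 (adjusted p = 0.0337), endothelial markers, lower, without SA 2 (adjusted p = 0.0320), and erythroid markers, higher, without SA 1 or SA 2 (adjusted p = 0.0458 and 0.0467), while without SA 4 the erythroid median was 0.07. Inflammatory cytokine genes had a median of -0.14 (adjusted p = 0.884), with Ccl5 at 1.20 and Ccr2 at -1.43, and the median ran from -0.24 without Ctrl 2 to -0.00401 without Ctrl 3. Antigen presentation (median -0.07, adjusted p = 0.491), cell cycle (median 0.04, adjusted p = 0.928), p53 targets (median 0.02, adjusted p = 0.931), the unfolded protein response (median 0.00, adjusted p = 0.931), ribosomal proteins (median -0.08, adjusted p = 0.240), sex-biased genes (median -0.01, adjusted p = 0.851) and markers of other tissues (median -0.19, adjusted p = 0.155) did not pass either. Without Ctrl 4 antigen presentation and ribosomal proteins passed, both lower (adjusted p = 0.0189 and 0.000303). Sex-biased genes passed without Ctrl 1, lower, and without Ctrl 2, higher (adjusted p = 0.0309 and 0.0477), and markers of other tissues, lower, without Ctrl 1 or SA 1 (adjusted p = 0.0413 and 0.0160). Ccnd1 of the cell cycle list, at -1.03, passed with DESeq2 (adjusted p = 0.0170), and Hnf4a of the hepatocyte markers, at 0.61, passed over its list alone. Of the 21 lists that did not pass, 14 had a median that changed sign when some library was left out.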

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

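The tests of a single control library, stellate cells, hepatocyte share, pooled T cell genes, sex, the Cyp2c paralogs and other splits of the libraries were chosen after the results were seen. Dixon's test was run on 264 groups of 4 libraries and marked 15, where chance gives about 1 in 20, that is 13.2. SA 4 had 28184001 total counts against 14114145 to 15922829 in the other SA libraries. The circadian list deviated by -0.31 in Ctrl 1, against -0.03 to 0.01 in the other Ctrl libraries. Of the 13 single genes, 5 stood apart in SA 1, namely Adgrv1 (9.32 CPM), Col3a1 (55.3 CPM), Mt1 (318.4 CPM), Timd4 (8.92 CPM) and Spp1 (56.9 CPM). In Ctrl 1, Saa4 (324.7 CPM) and Krt19 (4.37 CPM) stood apart, in Ctrl 3 Igha (1.33 CPM) and Aox1 (147.5 CPM), and in Ctrl 2 Sult1e1 (12.3 CPM). In SA 3 Cryab (3.73 CPM) stood apart, and in SA 4 Lyve1 (10.8 CPM) and Srebf2 (59.2 CPM).

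The matrix genes were lower in SA with a median log2 fold change of -1.10. Gene length and GC content argue little for it, since the median was -1.14 after a smooth fit on both over 29 of 29 members. Stellate markers fell by less, and their mean of -0.25 lay 0.84 ± 0.15 (SE over members) above the matrix mean. Members come from the same 8 libraries and are not independent, with an estimated correlation of 0.60 in the matrix list. That SE does not measure the spread between libraries. The smaller fall of the listed markers goes against fewer stellate cells as the whole cause but does not settle it. Whether Ctrl 1 alone makes the difference cannot be told apart from a group difference, because without it the median was -0.61 with 27 members still negative, but the list mean over 7 libraries gave p = 0.0857 (exact two-sided permutation test). A lower matrix expression after AAV2/9-SA, which the design names, remains open and may or may not hold beyond these libraries.

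Tested lymphocyte genes were higher in SA, with a mean log2 fold change of 0.82 ± 0.29 (SE) over 18 members of the T, NK, B and plasma lists. This SE is taken over members, which are not independent. Cd8a, Gzma and Ighg2c among them were low in Ctrl and entered the test through their SA counts. Blood left in the tissue is argued against, since with hemoglobin counts as a covariate the mean was 0.78. A lower share of hepatocyte RNA alone would raise the markers of other non-hepatocyte cells as well. The 70 markers of cholangiocytes, stellate cells, endothelium, Kupffer cells, recruited macrophages and neutrophils had a mean of -0.29 ± 0.08 (SE over members). The Kupffer markers among them had 0.40. The bile duct, stellate, recruited macrophage and neutrophil lists in this pool had already been called lower. Their own changes may set the mean, so it cannot decide on the share of hepatocyte RNA. More T cells of all kinds would raise the genes shared by T cells along with Cd8a. The pooled CPM of 7 such genes had a log2 ratio of -0.0630 ± 0.383 (SE; exact two-sided permutation test, p = 0.8286), below Cd8a by 2.85 ± 0.59 (SE). Zap70 made up 67.1% of those counts, and without it the ratio was 0.34 ± 0.31 (SE), below Cd8a by 2.44 ± 0.55 (SE). Cd8a had the smallest p of its list and was near the floor in Ctrl. A gene picked for its rise is likely to exceed other genes, and these SEs leave that out. The comparison therefore cannot decide whether more T cells of all kinds explain the rise of Cd8a. Whether the number or the state of CD8 T cells or B cells differed after AAV2/9-SA is not analysed here.

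Cyp2c40 was higher in SA and Adgrv1 lower. A sex difference is argued against by the summed CPM of 4 Y-linked genes, which was at least 159.3 in every library. Reads leaking from Cyp2c67 or Cyp2c68 are argued against, since the log2 fold change of Cyp2c40 exceeded that of Cyp2c68 by 2.59 ± 0.37 (SE), but sharing with Cyp2c69, itself at 2.48, stays open. For Adgrv1, whose longest transcript has 19.3 kb, gene length is argued against by a median of 0.14 over 300 genes with a transcript of 10 kb or more. The real split called 2 genes and the highest of the other splits 1, so 1 of 35 splits gave as many, the smallest share they allow. This count cannot settle whether chance made the 2 calls, since the margin is 1 gene and both calls end without Ctrl 4. At an unadjusted p under 0.05 chance cannot be excluded either. The real split gave 767 genes, the highest of the others 1818, and 8 of 35 splits as many. The 5 splits that put Ctrl 1, Ctrl 2 and SA 4 together gave 1738, 1107, 1818, 1687 and 293 genes, and whether they share a structure was not tested.

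The number of lists called does not stand apart from other splits of the libraries. The real split called 17 lists, 9 of 35 splits called as many, and the highest of the others called 21, so chance cannot be excluded. Of the 38 lists, 2 (T and NK cells, B and plasma cells) had their smallest p in the real split, where chance gives 1.09. The matrix list had a p as small in 5 of 35 splits. For the circadian and stellate lists this held in 2 splits each, for NRF2 targets in 15. It held in 5 splits each for recruited macrophages and Kupffer cells, and in 4 each for lipogenesis and triglyceride synthesis. Bile duct markers had it in 7, neutrophil markers in 8, acute phase and fatty acid uptake genes in 10 each and heat shock in 12. Cytochrome P450 and transferase genes had a p as small in 18 splits and mitochondrially encoded genes in 27.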

How the results depend on the processing

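Of the 1722 values of 91 named genes under the alternatives, 1668 kept their direction and side of the threshold, 24 moved past it, 11 dropped below it and 19 reversed. Only Cyp2c40 and Adgrv1 passed in the main test, so the 11 drops are all theirs. The 1668 therefore says little about how stable these 2 calls are. The mitochondrial covariate was chosen after seeing the data. Where a cause is not given below, the cause was not tested. Genes higher in SA, 1 in the main test, numbered 3 without a low-count filter, 23 with DESeq2, 2 with limma-voom and sample weights, 0 with each of the 3 FPKM settings, and 0 to 13 when a library was left out (0 without Ctrl 4, 13 without SA 1). Genes lower in SA, 1 in the main test, numbered 5 without a filter, 39 with DESeq2, 2 with limma-voom, 3 with sample weights, 3 with each FPKM setting, 0 with the mitochondrial covariate, and 0 to 6 when a library was left out (6 without SA 1). Cyp2c40 is not in the FPKM table. With the FPKM settings neither main call was kept. With 38 lists, 7 higher and 10 lower, the estimated correlation gave 0 and 0, fry 1 and 0, and log2(FPKM + 1) with 34 lists 2 and 2 (acute phase and Kupffer higher, lipogenesis and matrix lower), while leaving out a library gave 6 to 9 higher and 7 to 11 lower.

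The labels do not say that replicate numbers pair the libraries. Deviations of same-numbered libraries correlated across genes at -0.02, -0.02, 0.22 and -0.22, which cannot show whether they were paired. With the replicate block 5 genes were lower and 1 higher, the 2 main calls among them and Apoa4, Anxa2, Ephb2 and Fads3 as the others, and every list call was as in the main test. RLE factors ended the heat shock call. The mitochondrial covariate ended the calls of mitochondrially encoded, NRF2 and xenobiotic genes and added oxidative phosphorylation and ribosomal proteins, and the filter of CPM of at least 1 added PPARalpha targets. With log2(FPKM + 1) the T and NK, neutrophil and bile duct lists could not be tested. That setting ended the calls of recruited macrophages (adjusted p = 0.14997), B and plasma cells (0.806), stellate cells (0.379), circadian genes (0.209), triglyceride synthesis (0.525), fatty acid uptake (0.251), mitochondrially encoded genes (0.209), NRF2 targets (0.0524), xenobiotic genes (0.806) and heat shock (0.372).

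Reversed values were all far from the threshold. Without Ctrl 2 Acaca had -0.265, Acacb -0.202 and Csf3r -0.355, and without Ctrl 3 they had 0.00904, 0.116 and 0.0957, the ends of their ranges when a library was left out. With sample weights Acaca had 0.0798, Acacb 0.101 and Slc4a1 -0.95. Acacb had 0.0705, 0.0528 and 0.0705 with log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, where Cidec had 0.51, 0.56 and 0.51, Pparg 0.0148, 0.239 and 0.0148, and Hsp90aa1 0.77, 0.78 and 0.77.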

Other observations

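All genes and tables in this part were chosen after their values were seen. Besides the 2 genes past the threshold, 5 had an adjusted p under 0.1 (edgeR). Ephb2, an ephrin receptor, was at 27.7 ± 10.2 CPM in Ctrl and 4.03 ± 3.02 CPM in SA (SD, n = 4), with a log2 fold change of -2.79 ± 0.44 (SE; adjusted p = 0.0819). Fads3, of the same gene family as Fads1 and Fads2, was at 34.8 ± 4.30 CPM in Ctrl and 14.4 ± 4.34 CPM in SA, with -1.28 ± 0.20 (SE; edgeR, adjusted p = 0.0819). Slco2a1, a prostaglandin transporter, was at 26.4 ± 4.66 CPM in Ctrl and 63.0 ± 16.6 CPM in SA, with 1.25 ± 0.21 (SE; edgeR, adjusted p = 0.0972). The other genes were Cd8a and Ighg2c. Ephb2 and Fads3 passed with DESeq2 (adjusted p = 0.00268 and 2.59e-05), without a low-count filter (0.00318 and 0.0120), with the replicate block (0.0126 and 0.0430), with limma-voom and sample weights (0.0191 and 0.0267) and without SA 1 (0.00621 each), and Ephb2 also with limma-voom alone (0.0482). Slco2a1 passed with DESeq2 (adjusted p = 9.70e-05), without a filter (0.0131) and without SA 1 (0.00621).

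The FPKM table and the count table differ for some genes. In the FPKM table Ilkap was at 22.6 ± 3.32 in Ctrl and 0.451 ± 0.0327 in SA (SD, n = 4), while its counts gave 31.52 and 31.75 CPM. Acaca had 0.476 to 2.002 FPKM while its counts were 1383 to 2954 per library.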
